A study of Mus musculus with 14 samples.

How the data were processed

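The deposited table holds expected counts per Ensembl gene for each library; per the submitters' processing notes, GRCm38, HTSeq and DESeq2 1.42.1 were used, and the role of each is not given in the sources used here. Between 5.09% and 5.76% of the values of a library were fractional, so the expected counts were rounded to whole counts before use. The authors also deposited 6 tables of comparisons with log2 fold changes and, per the file headers, p-values and adjusted p-values in the column layout of limma; the model behind these log2 values and p-values is not given in the sources used here. Per the labels' protocols, RNA was extracted with RNeasy kits and libraries were made with NEBNext Ultra II.

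Groups were read from the sample titles, with OA in the titles taken as C18:1 and OAL as C18:1-leucine. For 2 libraries the treatment tag disagreed with the title, and alternatives with groups from the tags and without these libraries were computed. The letters of the authors' deposited tables were matched to groups by the highest correlation of fold changes, since no key is given in the sources used here. Gene symbols and coordinates came from the GENCODE mouse release M21 annotation of GRCm38, which held 45143 of the 45706 gene identifiers.

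Genes were kept by edgeR's filterByExpr with a minimum count of 10, a minimum total of 15 and a smallest group of 3, which left 15674 genes. All 14 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood F test, two-sided), and p was adjusted by Benjamini and Hochberg over the tested genes of a comparison, with a threshold of 0.05. Comparisons, tests, gene lists and the choice of named genes were fixed before the data were examined. The splits behind the opposite shares against MASH, and the tests and settings marked below as chosen later, were not among these. Intervals of fold changes are 95% intervals from the same fit. Under TMM, relative log expression and DESeq2 scaling the median log2 fold change of all genes lay between −0.02 and 0.013. CPM is the count of a gene relative to the TMM-scaled library size, in the usual unit of that name, averaged over the libraries of a group, and per-library scores used a prior count of 2. A gene with no counts in a group was given a bound from a floor of 3 counts over that group, and a gene with up to 3 counts a pooled ratio with an exact binomial interval.

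The named genes of each of the 4 main comparisons were the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 1 CPM in the higher group, a symbol that is not a clone name and no overlap between the groups. To these were added up to 4 genes with the smallest p of each list, the 10 genes with the smallest p where fewer than 10 passed, and Ccl2 and Ppara. From these the text names a part.

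The 31 gene lists cover lipid metabolism, bile acids, amino acids, matrix, inflammation, liver cell types, sex-biased genes, stress responses, the clock and neighbouring tissues. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 31 lists of a comparison, beside an estimated correlation and fry. Some genes stand in more than 1 list: Baat in the bile acid and N-acyl lists, Cyp7b1 and Slco1a1 in the bile acid and male-biased lists, and Acot3 in the PPARα and female-biased lists.

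On simulated counts drawn with the means and depths of the real libraries, edgeR recovered 32.8%, 83.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold among 15509 tested genes in the layout of MASH against chow, with 7 false calls of 148. In the layout of C18:1-leucine against MASH it recovered 29.9%, 71.6% and 97.0% among 15512 genes, and in that of C18:1-leucine against C18:1 37.3%, 82.1% and 95.5% among 15540 genes. In the 4 layouts the list whose genes were doubled was called, and of the other lists 1, 0, 0 and 0 were called. Each gene was drawn independently, so the simulated lists lacked the correlation between genes of real libraries. These counts therefore do not give the rate of false list calls in the real data, where other splits of the libraries called up to 23 lists. The shares of genes recovered likewise leave out differences that many genes of a library share. The alternatives were relative log expression scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights, the compared groups fitted alone, a replicate block, each library left out, groups from the tags, both libraries with disagreeing labels left out and a 2-fold minimum. Shares affected by shared libraries were set beside 40 simulations in which neither compound had an effect, also with each gene drawn independently.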

Results

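RNA of mouse liver was sequenced in 14 libraries from male C57BL/6J mice in 4 groups. Mice entered the study at 8 weeks of age and were fed standard chow or a MASH diet, which is used to bring on metabolic dysfunction-associated steatohepatitis (a fatty liver with inflammation and scarring), for 16 weeks. Mice on the MASH diet were then treated for 6 more weeks with vehicle, with C18:1 (a monounsaturated fatty acid, abbreviated OA in the titles) or with C18:1-leucine, in which the amino acid leucine is coupled to that fatty acid. The chow group held 4 libraries, the MASH group 3 (replicates 2, 3 and 4), the C18:1 group 4 and the C18:1-leucine group 3 (replicates 1, 2 and 4). Doses are not given in the sources used here, and the titles do not say whether the mice of the MASH group received the vehicle. The libraries of a group carry different numbers, but the labels do not say that each came from a separate mouse. P-values therefore measure only the spread between these libraries. Between pairs of libraries of a group the chi-square per gene was 27.6 to 175.2, where counting error alone gives about 1. Repeat sequencing of the same library is thus argued against. Several preparations from the same liver are not excluded, so the spread may still be partly technical. Total counts ran from 33821874 in C18:1 replicate 2 to 51107248 in C18:1-leucine replicate 1, and 15674 of 45706 genes had enough counts to be tested. Counting intervals and count floors cover counting error only.

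The treatment tags of 2 libraries disagreed with their titles. C18:1 replicate 1 was tagged with diet alone, and C18:1-leucine replicate 1 was tagged as C18:1. Groups were taken from the titles throughout. On the first principal component, which held 57% of the variance of the tested genes, chow libraries lay at −74 to −66.2. The C18:1-leucine libraries lay at −11.8, −10.7 and 17.3, the MASH libraries at 14.2, 18.1 and 50.6, and the C18:1 libraries at 25.2 to 69.8.

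Transcripts of neighbouring tissue and of rarer cell types were unevenly spread over the libraries. Given as CPM of all counts of a library, pancreatic enzyme transcripts reached 1010 CPM in C18:1-leucine replicate 2 and 202 CPM in chow replicate 2, against 3.80 to 9.31 CPM in the other libraries. Erythroid transcripts, chiefly globins, came to 1123, 1215 and 639 CPM in the C18:1-leucine libraries and to 303 to 783 CPM in the other groups. Neutrophil transcripts were highest in C18:1-leucine replicate 1, at 56.3 CPM against 3.61 to 31.8 elsewhere. Bile duct (cholangiocyte) transcripts reached 449 CPM in MASH replicate 4, 560 and 471 in C18:1 replicates 1 and 3, and 234 in C18:1-leucine replicate 4, against 40.9 to 182 CPM in the other libraries.

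**Figure D1:**
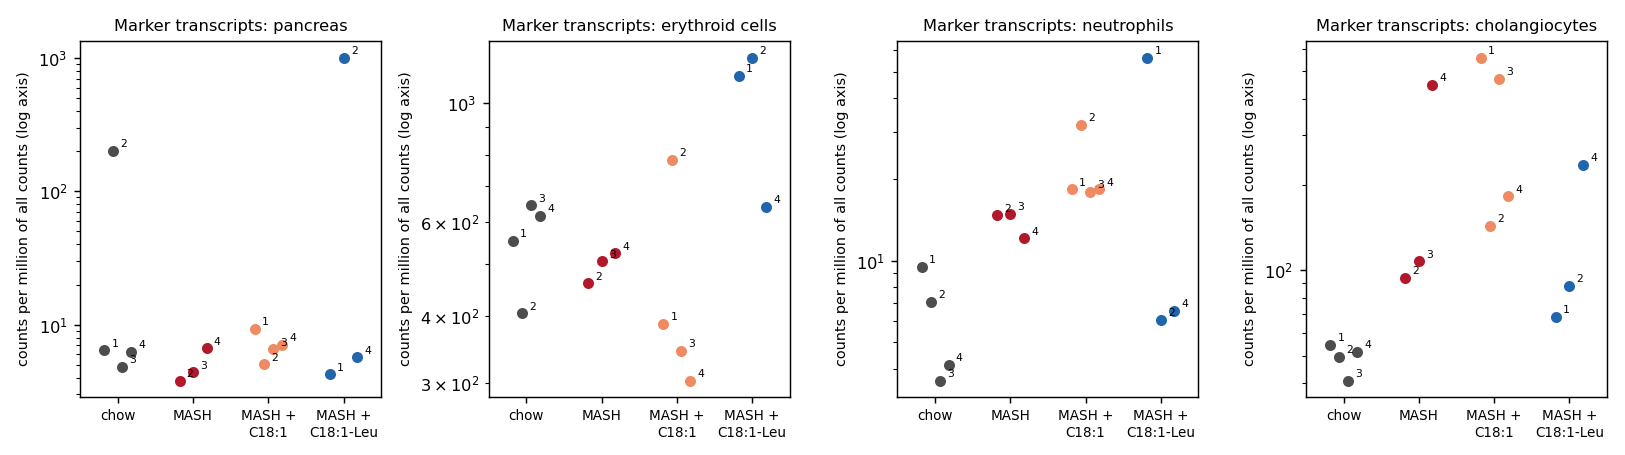
Marker transcripts of 4 neighbouring tissues or rarer cell types in each library, as CPM of all counts on a log axis, with libraries grouped and each point marked with its replicate number. Pancreatic transcripts stood at 1010 CPM in C18:1-leucine replicate 2 and at 202 CPM in chow replicate 2, and erythroid transcripts at 1123 and 1215 CPM in C18:1-leucine replicates 1 and 2.

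The comparison of MASH with chow asks how the transcriptome of livers on the MASH diet differed. No treatment period is given for the chow mice in the sources used here. Age at collection and handling may therefore differ along with the diet. Genes of recruited, lipid-handling macrophages, of matrix remodelling, of chemokine signalling and of lipid droplets were higher on the MASH diet, while genes of cholesterol synthesis and of hepatocyte function were lower. With an estimated correlation the macrophage list was called (adjusted p = 0.0207) and the others were not, at adjusted p of 0.123 for matrix, 0.0627 for chemokines, 0.0760 for lipid droplets, 0.0810 for cholesterol and 0.289 for hepatocytes. Mmp12, a macrophage elastase, stood at 52.2 ± 13 CPM (SD, n = 3) in MASH livers and at 0.465 ± 0.106 (n = 4) in chow livers, a log2 fold change of 6.80 ± 0.39 (SE; adjusted p = 9.81e-07, edgeR). Gpnmb, a marker of lipid-laden macrophages, rose from 0.207 ± 0.067 to 57.3 ± 22.4 CPM. Sqle, an early and rate-limiting enzyme of the sterol branch of cholesterol synthesis, fell from 59.6 ± 30.9 to 2.33 ± 2.06 CPM, a log2 fold change of −4.67 ± 0.71 (adjusted p = 0.000465).

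Of 15674 genes, 5563 (35.5%) passed an adjusted p of 0.05, 3200 of them higher and 2363 lower in MASH, and 2075 changed at least 2-fold. Among the largest rises with no overlap between the groups, Cidea, a lipid droplet protein, rose by 7.24 ± 0.70 on the log2 scale, Timp1 (an inhibitor of matrix metalloproteinases) by 5.93 ± 0.62, Tubb2b by 5.91 ± 0.87, Ephb2 by 5.75 ± 0.75 and Ly6d by 5.58 ± 0.56, with Ly6d at 84.6 ± 7.40 against 1.78 ± 1.15 CPM. Sprr1a had no count in the 4 chow libraries and was at least 98.0-fold higher in MASH, with the floor of 3 counts set over the chow group. Aqp7, a glycerol channel, had 2 counts in all chow libraries and was 206-fold higher (95% counting interval 56.6 to 1706), and Fabp3 was 99.4-fold higher (27.2 to 827). The largest falls were those of Moxd1 (−8.72 ± 1.85), Cyp2c69 (−4.68 ± 1.11), Sqle, Cyp2c40 (−4.59 ± 1.04), the major urinary protein genes Mup12 (−4.38 ± 0.64), Mup7 (−4.25 ± 0.90), Mup1 (−4.15 ± 0.67) and Mup16 (−4.08 ± 0.85), the serpin gene Serpina1e (−4.17 ± 0.45) and the steroid dehydrogenase gene Hsd3b5 (−3.89 ± 0.92). Mup, Cyp2c and Serpina1 genes belong to families of near-identical copies, so their counts are uncertain where reads fit several members. The calls of these 20 genes were kept when any 1 library was left out.

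Lipid droplet genes rose: 11 of 13 passed and none fell, with a median log2 fold change of 1.73 (adjusted p = 0.0760, camera with an estimated correlation). Cd36, a fatty acid transporter, rose by 1.82 ± 0.16 (280 ± 29.4 against 79.4 ± 13 CPM), Cidec by 4.41 ± 0.52 and Fabp4 by 2.19 ± 0.27. Cholesterol synthesis and uptake fell, with 23 of 24 genes lower and a median of −1.84 (adjusted p = 0.0810, camera with an estimated correlation). Cyp51 fell by 2.88 ± 0.29, Msmo1 by 3.43 ± 0.39, Stard4 by 2.39 ± 0.25 and Srebf2, the transcription factor that drives the pathway, by 0.90 ± 0.11. Genes of fatty acid synthesis went both ways and were not called as a list (adjusted p = 0.551, camera). Scd1, the main desaturase of the liver, rose by 3.00 ± 0.51, Elovl6 by 1.05 ± 0.18 and Acaca by 0.89 ± 0.16, whereas Acly fell by 0.66 ± 0.14. Targets of PPARα, the nuclear receptor that drives fatty acid oxidation, did not shift as a group: 6 of 36 were higher, 3 lower and 27 did not pass (adjusted p = 0.439), with a median of −0.10 and a mean of 0.10. Without MASH replicate 2 the list passed as lower (median −0.24, adjusted p = 0.0138). The number of lower PPARα targets was 11 without MASH replicate 2, 5 without C18:1 replicate 1, 1 without chow replicate 1, chow replicate 3 or MASH replicate 3, and 0 without MASH replicate 4. Pdk4 (2.16 ± 0.38), Acot2 (1.79 ± 0.36), Fgf21 (2.95 ± 0.68) and Aldh3a2 (1.25 ± 0.22) were among those that rose.

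Inflammatory and matrix genes rose together. Of the recruited macrophage list 16 of 18 genes rose and none fell, with a median of 2.52. Besides Mmp12, Itgax rose by 4.30 ± 0.26, the galectin gene Lgals3 by 3.28 ± 0.21 and Lpl by 3.07 ± 0.20. Chemokines, cytokines and adhesion genes rose in 18 of 23 cases (median 1.99), with Il1rn at 2.33 ± 0.21 and Cxcl16 at 1.46 ± 0.18. Ccl7 had 3 counts in all chow libraries and was 33.3-fold higher (11.1 to 164). Collagen and matrix genes rose in 27 of 29 cases (median 1.92), with Mmp13 at 5.53 ± 0.46, Thbs1 at 3.08 ± 0.33 and Col4a1 at 1.75 ± 0.18. All 16 interferon response genes rose (median 1.49), among them Oasl2 by 2.03 ± 0.14 and Oas1a by 2.19 ± 0.21, and 15 of 17 cell cycle genes rose (median 2.02), among them Mki67 by 2.46 ± 0.41. Stellate cell genes rose in 8 of 12 cases (median 0.72), with Pdgfrb at 1.81 ± 0.31, and T and NK cell genes in 4 of 15 (median 0.98), with Pdcd1 at 3.67 ± 0.86. With an estimated correlation the adjusted p was 0.0755 for interferon genes, 0.444 for the cell cycle, 0.444 for stellate cells and 0.632 for T and NK cells. The T and NK cell list also ended above the threshold without chow replicate 4 (adjusted p = 0.0554), MASH replicate 2 (0.0510) or MASH replicate 3 (0.0701). Without MASH replicate 4, 9 cell cycle genes were higher, and 2 stellate cell genes, which numbered 5, 4, 5 and 4 without chow replicates 1 to 4 and 4 without MASH replicate 2.

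Hepatocyte genes moved the other way. Of 20 hepatocyte function genes 15 fell and none rose (median −0.76), including albumin (Alb, −0.73 ± 0.15), the liver transcription factor gene Hnf4a (−0.72 ± 0.17) and the urea cycle gene Otc (−0.61 ± 0.13). Bile acid synthesis and transport fell in 9 of 20 cases (median −0.39), with the bile acid importer Slc10a1 at −0.95 ± 0.14 and Cyp7b1 at −2.06 ± 0.31. Branched-chain amino acid catabolism fell in 11 of 19 (median −0.26), with Acadsb at −0.71 ± 0.10 and Bcat2 at −0.67 ± 0.15. All 16 nuclear-encoded respiratory chain subunits fell, by a median of −0.31. Male-biased liver genes fell in 7 of 12 cases (median −0.87), with Cyp2d9 at −1.17 ± 0.15. Stress response genes had a median of −0.79 (−0.3 without chow replicate 1) with 2 of 15 lower, chiefly the asparagine synthetase gene Asns at −3.72 ± 0.44, and clock genes a median of −0.70 with 4 of 14 lower and Npas2 higher at 2.82 ± 0.61. With an estimated correlation the adjusted p of these 7 lists was 0.289, 0.123, 0.444, 0.444, 0.189, 0.444 and 0.437 in the order named. Without MASH replicate 4, 9 hepatocyte, 7 branched-chain amino acid and 10 respiratory chain genes were lower, and without chow replicate 3, 7 branched-chain amino acid genes. The number of lower stress response genes was 1 without chow replicate 1 or MASH replicate 4, 5 without chow replicate 4 or MASH replicate 3 and 6 without chow replicate 2 or 3. That of lower clock genes was 1 without chow replicate 3 or MASH replicate 4, 2 without chow replicate 4 and 8 without MASH replicate 3.

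The remaining 13 lists did not pass in MASH against chow. The adjusted p was 0.438 for N-acyl amino acid enzymes, 0.500 for Kupffer cells, 0.115 for B cells, 0.399 for neutrophils, 0.125 for cholangiocytes, 0.886 for endothelial cells, 0.220 for female-biased genes, 0.386 for acute phase and for NRF2 genes, and 0.399 for immediate early genes. B cells passed without chow replicate 2 (0.043) or MASH replicate 3 (0.0294). The cholangiocyte median of 1.58 passed without MASH replicate 2 (0.04225) or 3 (0.02745) and was 0.35 without MASH replicate 4. Among the members that passed were Naaa (0.73 ± 0.16) and Napepld (1.10 ± 0.28) with Baat lower (−0.63 ± 0.11), the Kupffer cell gene Cd5l (1.47 ± 0.34), the B cell gene Cd22 (1.64 ± 0.21) and the neutrophil gene Csf3r (1.19 ± 0.25). Saa3 of the acute phase stood at 2.55 ± 0.48, Slc7a11 of the NRF2 list at 4.23 ± 0.82, Ier3 of the immediate early genes at 1.23 ± 0.25 and the female-biased gene Cyp17a1 at −1.19 ± 0.31. No pancreatic or erythroid gene passed (adjusted p of the lists 0.399 and 0.354), and of 2 adipose genes (0.439) Cfd was higher (5.44 ± 0.83).

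Of these MASH calls, adjustment over the list alone gave 19 chemokine, 28 collagen, 16 macrophage, 11 lipid droplet and 16 interferon genes higher, and 23 cholesterol, 16 hepatocyte, 11 bile acid, 12 branched-chain amino acid and 8 male-biased genes lower. Adjusted over the list alone, 5 of 36 PPARα targets were higher and 2 lower.

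**Figure D2:**
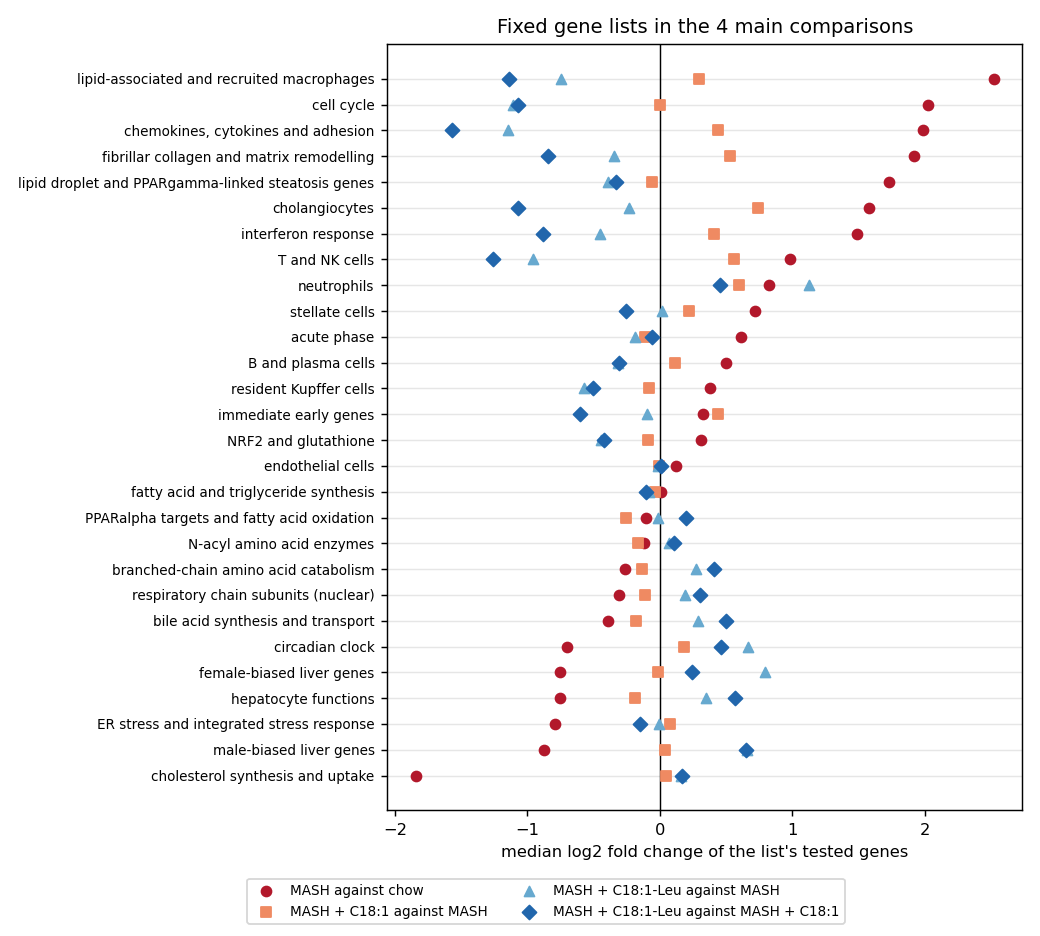
Median log2 fold change of the tested genes of each of 28 fixed gene lists in the 4 main comparisons, with 1 point per list and comparison and a vertical line at 0. The macrophage list had a median of 2.52 in MASH against chow and of −1.14 in C18:1-leucine against C18:1, and the bile acid list −0.39 and 0.50.

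The title of the series names Ccl2, which encodes the chemokine that draws monocytes into tissue, and the receptor PPARα. Ccl2 (ENSMUSG00000035385; GRCm38 chromosome 11, 82035571 to 82037453) stood at 0.141 ± 0.047 CPM in chow (n = 4), 3.51 ± 0.719 in MASH (n = 3), 4.05 ± 0.770 with C18:1 (n = 4) and 0.963 ± 0.244 with C18:1-leucine (n = 3). It rose by 4.61 ± 0.29 on the log2 scale in MASH against chow (adjusted p = 1.30e-06). The C18:1-leucine group was lower than the C18:1 group by a log2 fold change of −2.07 ± 0.25 (adjusted p = 0.00224), a call that was kept when any 1 library was left out. Against MASH the log2 fold change was −1.86 ± 0.26 with C18:1-leucine (adjusted p = 0.0315) and 0.21 ± 0.22 with C18:1 (95% interval −0.27 to 0.69, adjusted p = 0.846). The call of C18:1-leucine against MASH ended without chow replicate 2 (adjusted p = 0.0517), MASH replicate 3 (0.0817) or 4 (0.0714), or C18:1-leucine replicate 1 (0.109) or 2 (0.18). Transcripts of Ppara itself (ENSMUSG00000022383; chromosome 15, 85734983 to 85802819) stood at 142 ± 13.5, 133 ± 18.6, 121 ± 20.2 and 152 ± 21.1 CPM in the same order. They passed in none of the 4 comparisons, and C18:1-leucine against C18:1 gave 0.33 (95% interval 0.02 to 0.63, adjusted p = 0.129).

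**Figure D3:**
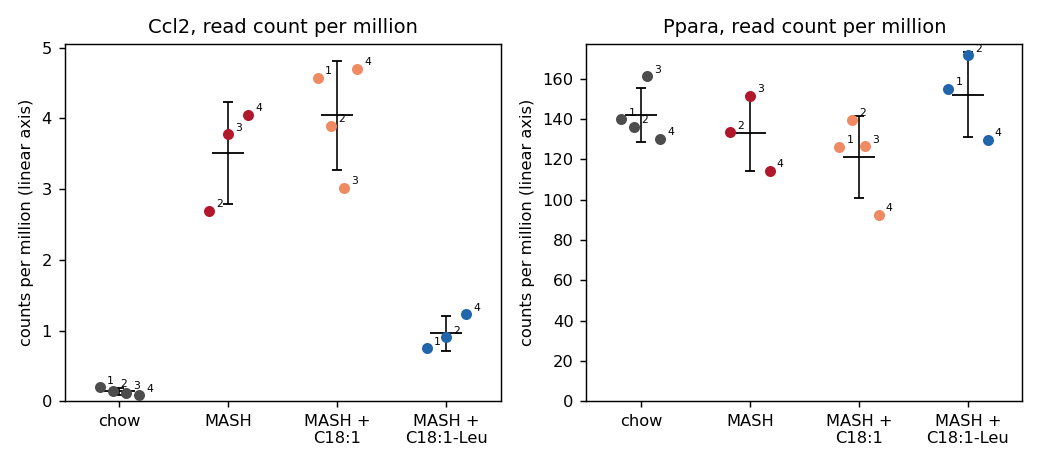
CPM of Ccl2 and Ppara in each library on linear axes from 0, with the group mean and SD as black bars and each point marked with its replicate number. Ccl2 averaged 3.51 in MASH, 4.05 with C18:1 and 0.963 with C18:1-leucine, while the Ppara means lay between 121 and 152.

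The comparison of C18:1 with MASH asks what the fatty acid alone did. No gene passed with edgeR, where the lowest adjusted p was 0.770 and 968 genes had an unadjusted p under 0.05, against 784 given by chance. limma voom also called 0 genes, and DESeq2 called 2. These were Agap2, higher by 0.96 ± 0.20, and the hepatic lipase gene Lipc, lower by a log2 fold change of −0.32 ± 0.07 (both DESeq2, adjusted p = 0.0268). In edgeR the genes with the smallest p were Lipc (−0.34 ± 0.07; 96.7 ± 3.89 against 122 ± 10.4 CPM), Cept1 (−0.35 ± 0.07), Agap2 (0.96 ± 0.20), Coq8a (−0.57 ± 0.13), Lgalsl (−0.55 ± 0.12), Hsd17b6 (−0.77 ± 0.18), Nmt2 (−0.35 ± 0.08), A1cf (−0.43 ± 0.10), 1700055D18Rik (−0.78 ± 0.19) and Lsm11 (−0.50 ± 0.12). On simulated libraries of this layout, 44.8%, 83.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. Genes were drawn independently there, which leaves out differences that many genes of a library share. Changes of these sizes with C18:1 are therefore not excluded.

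As lists, inflammatory and matrix genes were higher and hepatocyte genes lower with C18:1 than in MASH at the preset correlation, where 9 lists passed as higher and 6 as lower. The higher lists were collagens (median 0.53), chemokines (0.44), macrophages (0.29), T and NK cells (0.56), neutrophils (0.60), stellate cells (0.22), cholangiocytes (0.74), interferon response (0.41) and immediate early genes (0.44). The lower lists were PPARα targets (−0.26), bile acids (−0.18), branched-chain amino acids (−0.14), N-acyl amino acid enzymes (−0.16), hepatocyte functions (−0.19) and the respiratory chain (−0.11). None of the 15 was called with an estimated correlation, where the lowest adjusted p was 0.453, nor by fry (lowest 0.357). With the groups taken from the treatment tags, PPARα targets, neutrophils, the interferon response and immediate early genes kept call and direction. The direction of the other 11 of the 15 turned, collagens to −0.18 (adjusted p = 0.04215), hepatocyte functions to 0.16 (0.0182), T and NK cells to −0.17 (0.143) and macrophages to −0.07 (0.237). Among the members, Itgax stood at 0.59 ± 0.21, Oasl2 at 0.52 ± 0.14, Cd3e at 1.27 ± 0.43, Acot3 at −2.15 ± 0.65 and Pdk4 at −1.11 ± 0.37, none past the threshold. Adjusted over the list alone, 1 interferon gene was higher and 1 female-biased gene lower. MASH replicate 4 and C18:1 replicates 1 and 3 also carried the most cholangiocyte transcripts of these libraries. The cholangiocyte call ended without MASH replicate 2 (adjusted p = 0.0774) or 3 (0.237) or C18:1 replicate 1 (0.113) or 3 (0.186). The stellate cell call ended without the same 4 libraries (0.109, 0.171, 0.379 and 0.121), as did the call of N-acyl amino acid enzymes (0.149, 0.144, 0.101 and 0.0884). The neutrophil call ended without MASH replicate 3 (0.0584) or 4 (0.204) or C18:1 replicate 2 (0.414), and the immediate early call without C18:1 replicate 4 (0.140). Other medians moved with 1 library: without MASH replicate 2 that of PPARα targets was −0.08, of branched-chain amino acids −0.08 and of collagens 0.26, and without MASH replicate 4 collagens had 0.8, macrophages 0.49, stellate cells 0.39 and cholangiocytes 1.97. Without C18:1 replicate 1 collagens had 0.29, T and NK cells 0.34 and branched-chain amino acids −0.09, without C18:1 replicate 2 hepatocyte functions −0.37 and stellate cells 0.37, and without C18:1 replicate 4 the interferon response 0.21. Of the 16 lists not called, 7 were called without some library.

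The comparison of C18:1-leucine with MASH asks whether the conjugate changed livers on the diet. A small set of macrophage, matrix and chemokine genes was lower with C18:1-leucine. Ccl2 fell as given above, the collagenase gene Mmp13 fell from 6.64 ± 1.17 (n = 3) to 1.09 ± 0.435 CPM (n = 3), a log2 fold change of −2.61 ± 0.39, Mmp12 by 1.94 ± 0.31, Lgals3 by 1.31 ± 0.21 and Cd14, a co-receptor for bacterial lipopolysaccharide, by 1.12 ± 0.16. Atoh8 (−1.02 ± 0.16), Galnt6 (−0.95 ± 0.15), Iqgap1 (−0.86 ± 0.12) and Gramd1b (−0.82 ± 0.12) were also lower, and Zfp385b (0.83 ± 0.13; 14.1 ± 1.13 against 7.96 ± 0.673 CPM) was higher. With Gm20388, a clone-named gene lower in C18:1-leucine and added here after its values were seen, these made up the 11 genes past the threshold, 1 higher and 10 lower, at adjusted p of 0.0315 to 0.0447.

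The count of 11 depended on the tool and on single libraries. DESeq2 called 938 genes (410 higher and 528 lower) and limma voom 617 (230 higher and 387 lower), and 2836 genes had an unadjusted edgeR p under 0.05. The edgeR count was 0 without MASH replicate 3, C18:1-leucine replicate 1 or C18:1-leucine replicate 2, and 1, 2, 5, 5, 6 and 7 without chow 2, MASH 2, chow 3, chow 4, MASH 4 and chow 1. It was 20 without C18:1 replicate 2, 61 without C18:1 replicate 3 and 55 without C18:1-leucine replicate 4. No named gene kept its call with every library left out in turn.

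Among the lists, 8 were higher and 9 lower with C18:1-leucine against MASH at the preset correlation. None was called with an estimated correlation, where the lowest adjusted p was 0.0950, for chemokines. Chemokines had a median of −1.15 and 1 of 23 genes lower (14 adjusted over the list alone), macrophages −0.75 with 2 of 18 lower (8 over the list alone), and collagens −0.35 with 1 of 29 lower (5 over the list alone). With an estimated correlation the adjusted p was 0.122 for macrophages and 0.515 for collagens. Interferon genes had a median of −0.46, with Oasl2 at −0.74 ± 0.15 and 7 of 16 genes lower when adjusted over the list alone (adjusted p = 0.257 with an estimated correlation). NRF2 genes had a median of −0.44 with 4 of 11 lower over the list alone (0.122), and cell cycle genes −1.11 (0.438), T and NK cells −0.96 (0.437), Kupffer cells −0.57 (0.515) and lipid droplets −0.39 (0.438) were lower with no gene passing over all genes. Bile acid genes were higher with a median of 0.29, among them Slc10a1 at 0.74 ± 0.15, and 5 of 20 passed over the list alone (adjusted p = 0.122 with an estimated correlation). Branched-chain amino acid genes had a median of 0.27 and 10 of 19 higher over the list alone (0.257), male-biased genes 0.66 and 8 of 12 (0.122), the respiratory chain 0.19 and 6 of 16 (0.409), hepatocyte functions 0.35 and 0 of 20 (0.409), and cholesterol synthesis 0.16 and 1 of 24 (0.625). Clock genes had a median of 0.67 with 3 of 14 higher and 3 lower over the list alone (0.278), among them Bmal1 at −1.90 ± 0.42 and Per3 at 2.27 ± 0.58. Erythroid genes, most abundant in C18:1-leucine replicates 1 and 2, had a median of 1.25 and 7 of 7 higher over the list alone (0.257). PPARα targets were not called (median −0.01, adjusted p = 0.714), but were called higher without MASH replicate 2 (median 0.15, adjusted p = 0.0117) and lower without MASH replicate 4 (−0.14, 0.00103). Without MASH replicate 4 the collagen (adjusted p = 0.129), cell cycle (0.0751) and clock (0.0549) calls ended. The cholesterol and Kupffer cell calls ended without MASH replicate 2 (0.143 and 0.0707) or C18:1-leucine replicate 4 (0.0723 and 0.508), and the lipid droplet call without C18:1-leucine replicate 1 (0.191). Without MASH replicate 2 the collagen median was −0.58, and without MASH replicate 4 it was −0.13, with cell cycle at −0.24, macrophages at −0.46 and cholesterol synthesis at 0.34. The lipid droplet median was −0.2 without C18:1-leucine replicate 1 and −0.68 without 4, and that of Kupffer cells −1.1 and −0.15.

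The comparison of the 2 compounds asks whether coupling leucine to C18:1 changed the response. Both were given for 6 weeks, and doses were not given. Livers treated with C18:1-leucine had lower expression of macrophage, chemokine, interferon and T cell genes and higher expression of bile acid, amino acid, respiratory chain and hepatocyte genes than livers treated with C18:1. With an estimated correlation the chemokine and bile acid lists were called (adjusted p = 0.0471 for each) and the others were not, at adjusted p of 0.104 for macrophages, 0.157 for interferon genes, 0.293 for T and NK cells, 0.176 for branched-chain amino acids, 0.293 for the respiratory chain and 0.216 for hepatocytes. Lgals3 stood at 19.3 ± 3.59 CPM (n = 3) against 58.4 ± 11.2 (n = 4), a log2 fold change of −1.60 ± 0.20 (adjusted p = 0.00256), and the interferon-induced gene Oasl2 at 8.68 ± 1.43 against 20.9 ± 2.91 CPM, −1.26 ± 0.14 (adjusted p = 0.00224). The bile acid importer Slc10a1 stood at 489 ± 56.7 against 280 ± 51.6 CPM, 0.80 ± 0.14 (adjusted p = 0.00458). In all, 2544 genes (16.2%) passed with edgeR, 1151 higher and 1393 lower with C18:1-leucine, and 643 changed at least 2-fold.

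The largest rises were those of Cela2a (8.12 ± 2.46), Moxd1 (6.57 ± 1.36), Hsd3b5 (3.46 ± 0.82), Acot3 (2.80 ± 0.66), Mup7 (2.75 ± 0.77), Mup16 (2.62 ± 0.75), Mup9 (2.55 ± 0.77), Mup1 (2.19 ± 0.58), Mup12 (1.96 ± 0.55) and Cyp2c54 (1.96 ± 0.31; 156 ± 39.6 against 40.3 ± 20.1 CPM). Cela2a encodes a pancreatic elastase, and its mean of 41.3 ± 71.1 CPM came chiefly from C18:1-leucine replicate 2, without which it no longer passed (0.72, adjusted p = 0.882). The largest falls were those of Acod1, the itaconate-producing enzyme of activated macrophages (−3.02 ± 0.59), Sprr1a (−2.85 ± 0.73), Mmp13 (−2.71 ± 0.38), Tubb2b (−2.67 ± 0.65), Clec4e (−2.60 ± 0.65), Slc7a11 (−2.53 ± 0.67), Ypel4 (−2.52 ± 0.54), Fosb (−2.45 ± 0.60), Slamf8 (−2.37 ± 0.32) and Fabp3 (−2.33 ± 0.67). Of these 20 genes, Cyp2c54, Acod1, Mmp13 and Slamf8 kept their calls with any 1 library left out. The other 16 lost it without at least 1 library, 14 of them without C18:1-leucine replicate 1 (adjusted p of 0.0536 to 0.357) and 13 without C18:1-leucine replicate 2 (0.0546 to 0.882). Without C18:1 replicate 1, 9 lost it (0.0531 to 0.115), and without C18:1 replicate 4, 10 lost it (0.0514 to 0.105). Without C18:1 replicates 2 or 3, 4 each lost it (up to 0.0736 and 0.0905), without MASH replicates 2, 3 or 4, 2, 3 and 4 lost it (up to 0.0736, 0.0721 and 0.0739), and without chow replicate 3, 1 lost it (0.0540).

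Chemokines, cytokines and adhesion genes were lower with C18:1-leucine in 17 of 23 cases and higher in none (19 lower adjusted over the list alone), with a median of −1.57. Besides Ccl2, Il1rn stood at −1.57 ± 0.21, Cxcl16 at −0.93 ± 0.18 and Cxcl10 at −1.69 ± 0.35. Recruited macrophage genes were lower in 12 of 18 cases (13 over the list alone; median −1.14), with Itgax at −1.45 ± 0.22, Mmp12 at −1.94 ± 0.30 and Cd68 at −1.14 ± 0.20. Interferon genes were lower in 12 of 16 (15 over the list alone; median −0.88), with Gbp2 at −1.84 ± 0.30 and Oas1a at −1.21 ± 0.21. Collagen and matrix genes were lower in 13 of 29 (18 over the list alone; median −0.84), with Tgfb1 at −0.84 ± 0.14 and Col4a1 at −0.93 ± 0.18 (adjusted p = 0.327 with an estimated correlation). T and NK cell genes were lower in 8 of 15 (11 over the list alone; median −1.26), with Cd3d at −1.77 ± 0.39. Cell cycle genes had a median of −1.07, cholangiocyte genes −1.07 and immediate early genes −0.60, at adjusted p of 0.531, 0.610 and 0.577 with an estimated correlation. Cholangiocyte transcripts were most abundant in C18:1 replicates 1 and 3, and that list lost its call without either (adjusted p = 0.107 and 0.185) and without C18:1-leucine replicate 1 (0.120) or 2 (0.0737), and its median was −1.79 without 4. The immediate early call ended without C18:1-leucine replicate 2 (0.113), and its median was −1.18 without replicate 1 of that group and −0.36 without C18:1 replicate 4. From 0 to 6 of 17 cell cycle genes passed as lower when 1 library was left out. The number of lower chemokine genes was 10 without C18:1 replicate 4 or C18:1-leucine replicate 1 and 6 without C18:1-leucine replicate 2. That of collagen and matrix genes was 6 without C18:1 replicate 1, 4 without C18:1-leucine replicate 1 and 3 without C18:1-leucine replicate 2. That of T and NK cell genes was 1 without C18:1 replicate 1, C18:1 replicate 4 or C18:1-leucine replicate 4, 5 without C18:1-leucine replicate 1 and 2 without C18:1-leucine replicate 2.

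In the other direction, bile acid synthesis and transport was higher with C18:1-leucine in 11 of 20 cases and lower in none (12 over the list alone; median 0.50), with the uptake transporter genes Slco1b2 at 0.60 ± 0.10 and Slco1a1 at 1.82 ± 0.32 and the bile acid receptor gene Nr1h4 at 0.46 ± 0.11. Branched-chain amino acid catabolism, which degrades leucine among others, was higher in 16 of 19 cases (17 over the list alone; median 0.41), with Acadsb at 0.68 ± 0.10 (138 ± 14.4 against 86.6 ± 9.38 CPM), Auh at 0.46 ± 0.07 and Pcca at 0.32 ± 0.06. Nuclear-encoded respiratory chain subunits were higher in 14 of 16 (16 over the list alone; median 0.30), with Sdhb at 0.52 ± 0.10. Hepatocyte functions were higher in 6 of 20 (11 over the list alone; median 0.56), with Cyp2e1 at 0.79 ± 0.16 and Otc at 0.61 ± 0.12, and male-biased genes in 6 of 12 (7 over the list alone; median 0.65), with Mup3 at 1.44 ± 0.26 and Cyp2d9 at 0.74 ± 0.14. With an estimated correlation the adjusted p was 0.176 for male-biased genes. Of the PPARα targets, 4 of 36 were higher (4 over the list alone; median 0.20), and the list passed at the preset correlation (adjusted p = 0.00268; 0.610 with an estimated correlation). Eci2, an enzyme of fatty acid oxidation, stood at 0.45 ± 0.10. The list call ended without C18:1-leucine replicate 4 (adjusted p = 0.0657), and the median was 0.12 without C18:1 replicate 1. Erythroid genes were higher in 7 of 7 cases, with a median of 1.45 (adjusted p = 0.216 with an estimated correlation) and Alas2 at 0.64 ± 0.13. Of these 7, 1 was called without C18:1 replicate 1, 3 or 4 or without C18:1-leucine replicate 1 or 2. The number of higher bile acid genes was 4 without C18:1 replicate 1 or C18:1-leucine replicate 2, 5 without C18:1 replicate 4 or C18:1-leucine replicate 1 and 7 without C18:1 replicate 3. Without C18:1-leucine replicate 2, 6 branched-chain amino acid genes, 6 respiratory chain genes, 3 male-biased genes and 2 PPARα targets were higher, and without C18:1-leucine replicate 1, 5, 3 and 2 of the last 3 lists. Without C18:1 replicate 1 or 4, 6 respiratory chain genes and 2 PPARα targets were higher, and without C18:1 replicate 2, 11 hepatocyte genes.

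The other 16 lists were not called between the compounds, though 9 of them were called without some library. Lipid droplet genes had a median of −0.33, and were called lower without C18:1-leucine replicate 4 (median −0.68, adjusted p = 0.0116). Neutrophil genes had a median of 0.45, which rested on C18:1-leucine replicate 1, and were called lower without it (−1.98, adjusted p = 6.79e-05). Among the N-acyl amino acid enzymes, Glyat was higher (0.48 ± 0.10) and Naaa lower (−0.68 ± 0.17). The Naaa call ended without C18:1-leucine replicate 2 (adjusted p = 0.0861) or 4 (0.0503). No gene of fatty acid synthesis, endothelial cells or stellate cells passed.

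The count of 2544 rested on which libraries were used. It was 756 without C18:1-leucine replicate 2, 1260 without C18:1-leucine replicate 1, 1237 without C18:1 replicate 1 and 1238 without C18:1 replicate 4, and 593 without both libraries with pancreatic transcripts. It was 487 without both libraries whose tag and title disagreed, and 0 with those libraries regrouped by their tags.

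**Figure D4:**
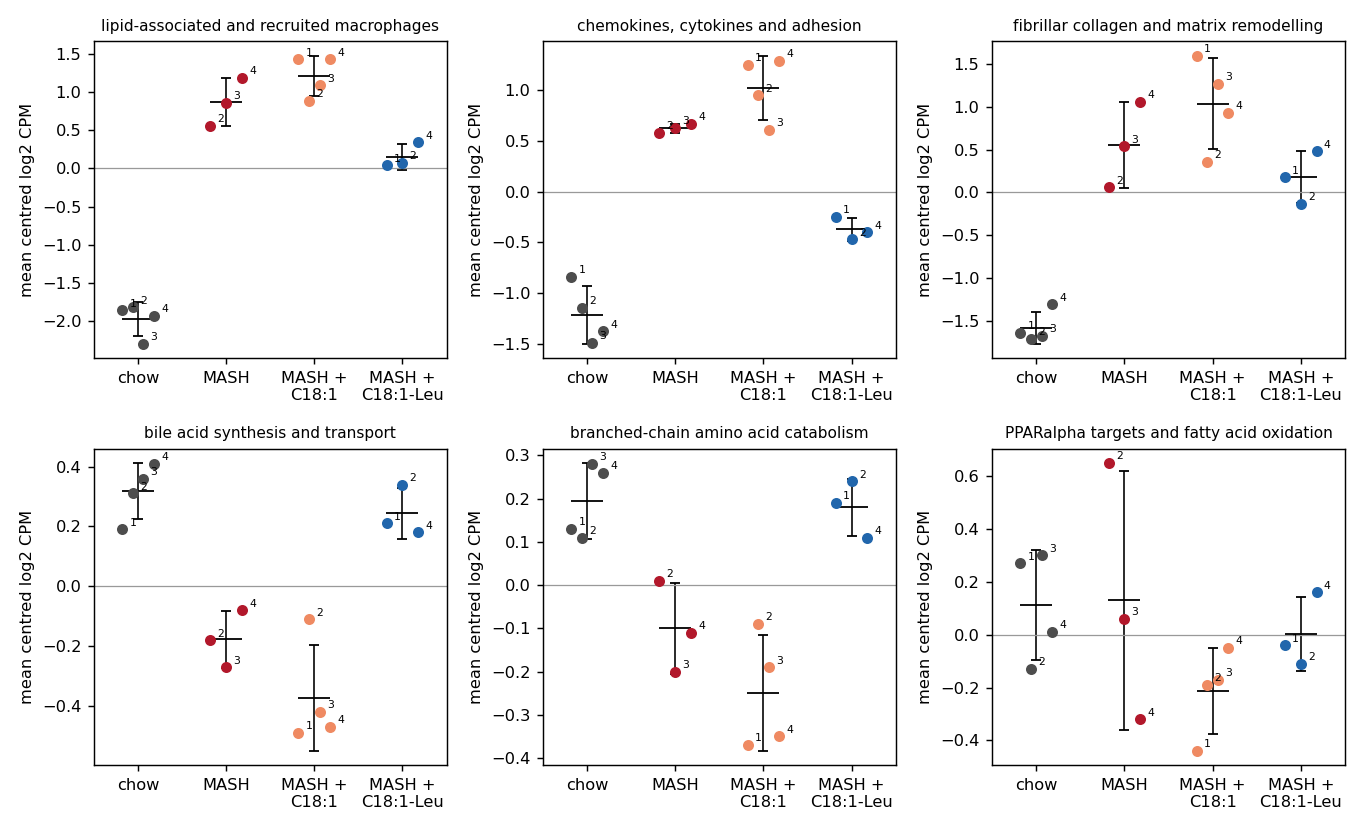
Scores of 6 gene lists in each library, as the mean over the list's genes of log2 CPM centred on each gene's mean, with group mean and SD as black bars and replicate numbers beside the points. The macrophage score averaged 1.21 ± 0.27 with C18:1 and 0.15 ± 0.16 with C18:1-leucine, and the bile acid score −0.37 ± 0.18 and 0.24 ± 0.09.

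A further comparison asked whether genes changed in MASH against chow differed between the compounds in the opposite direction. Of the 5563 genes that changed in MASH against chow, 95.4% had the opposite sign in C18:1-leucine against C18:1, 95.4% of the 3200 raised and 95.5% of the 2363 lowered genes. These comparisons share no library. Across genes, which are not independent replicates, the slope was −0.434 and Pearson's r −0.825. In 1 of 35 splits of the 7 compound libraries the share was as far from 50%, the real one (exact permutation p = 0.0286, two-sided, the smallest this design allows), and the other splits gave 5.0% to 93.7%. Against the mean of the C18:1 libraries, the share was 93.5%, 94.6% and 86.0% for C18:1-leucine replicates 1, 2 and 4. Of 2110 genes called in both comparisons, 2108 moved in opposite directions, 1251 raised by MASH and lower with C18:1-leucine and 857 lowered and higher, where independent lists would give 458 opposite and 445 in the same direction. That reference treats genes as independent, so it does not measure how unusual the 2108 are. Mmp12, Lgals3, Oasl2 and Ccl2 were raised by MASH and lower with C18:1-leucine than with C18:1, and Slc10a1, Acadsb, Otc and Mup3 were lowered by MASH and higher.

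Comparisons against the MASH libraries share those libraries with MASH against chow, which alone gives opposite signs. With C18:1 against MASH 21.8% of the 5563 genes had the opposite sign, where 40 simulations of unchanged groups gave 61.3% (59.3% to 62.6%). Other splits of the same 7 libraries gave 18% to 83.8%, and in 6 of 35 splits the share was as far from 50% as the real one (exact permutation p = 0.171, two-sided). With C18:1-leucine against MASH the share was 92.0%, where the simulations gave 60.4% (58.9% to 61.7%). In 1 of 10 splits of those 6 libraries, the real one, the share was as far from 50% (exact permutation p = 0.1, two-sided, the smallest this design allows). Neither set of splits was planned before the data were examined. No gene was called in the same direction for both compounds against MASH, and edgeR called 0 and 11 genes in these comparisons. Their fold changes correlated across genes at 0.033 with a covariance of 0.0051, against 0.529 and 0.052 in simulated unchanged groups that share the MASH libraries. With 3 MASH libraries the controls could not be divided into separate sets of at least 2 libraries. Part of the excess of the 92.0% over the simulations may come from the shared libraries. The 21.8%, the correlation and the covariance lay below the simulated values, which leave out differences that many genes of a library share.

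**Figure D5:**
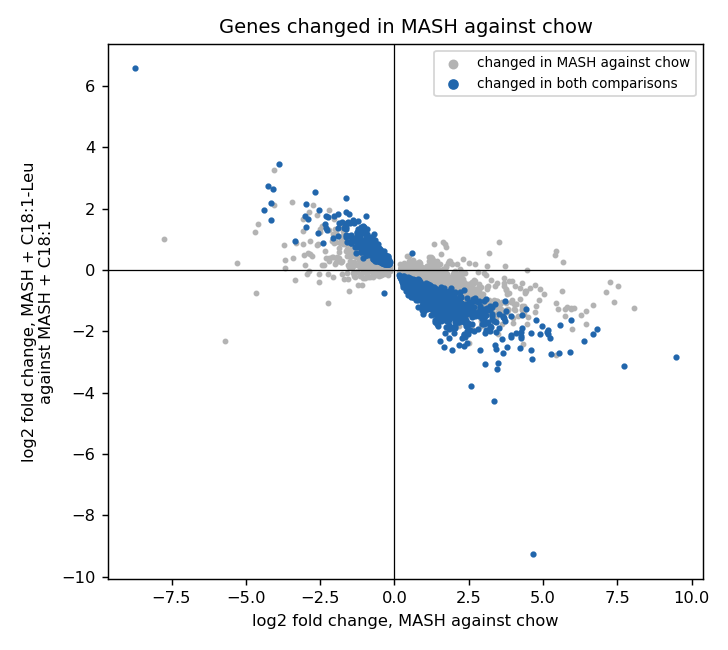
Log2 fold change in MASH against chow (horizontal) and in C18:1-leucine against C18:1 (vertical) for each of the 5563 genes changed in MASH against chow, with the 2110 genes called in both comparisons in blue. Of all points, 95.4% lie in the quadrants of opposite sign.

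Against chow, 8252 genes (52.6%) differed with C18:1 (4351 higher and 3901 lower) and 2276 (14.5%) with C18:1-leucine (1595 higher and 681 lower). Of the 5563 genes changed in MASH, 5327 (95.8%) were called in the same direction in the C18:1 group and 1977 (35.5%) in the C18:1-leucine group. These comparisons share the 4 chow libraries, which alone favours the same direction: 40 simulations in which the compounds left MASH livers unchanged gave 84.3% (82.7% to 85.4%) and 79.0% (78.2% to 80.3%). Genes were drawn independently there, so these ranges leave out differences that many genes of a library share. No splits of the libraries were set beside these shares, and their full spread without an effect is unknown. The C18:1-leucine count was 976 without C18:1-leucine replicate 4, 1338 without chow replicate 3, 1049 without both libraries with pancreatic transcripts and 653 with groups from the tags. These counts compare groups of 4 and 3 libraries, and the difference between the compounds was tested directly above.

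The authors' deposited tables of comparisons, which name the groups by the letters A to D without a key, were matched to the comparisons by their fold changes. With that matching, the authors' deposited table of C18:1 against MASH listed 0 genes with an adjusted p under 0.05 (lowest 0.676), that of C18:1-leucine against MASH 6 and that of C18:1-leucine against C18:1 2613, and those of MASH, C18:1 and C18:1-leucine against chow 5362, 8190 and 1662. In the authors' deposited tables the log2 fold change of Ccl2 was −1.86 in C18:1-leucine against MASH and −2.06 against C18:1. The median absolute difference between the authors' deposited tables and the fold changes computed here was 0.0077 to 0.0091 with groups from the titles and 0.051 to 0.136 with groups from the tags.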

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

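The per-library values below were picked out by a test for outlying samples in groups of 4, chow and C18:1, and every test weighed here except those of genes just above the threshold and of the erythroid median was chosen only after the result was seen. Of 308 groups tested, 19 had an outlying library, where chance gives about 15.4.

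In the C18:1 group, replicate 4 had an interferon response score of 1.31 (others 0.59 to 0.70), a stress response score of 0.32 (others −0.25 to −0.18) and a pancreatic score of −1 (others −1.31 to −1.26). Replicate 1 had 75.3 CPM of Cidea (others 34.1 to 40.4), and replicate 3 had 4.85 CPM of Acot3 (others 1.96 to 2.25). Replicate 2 had 1.08 CPM of Fabp3 (others 2.72 to 2.89), 1.76 of Cyp2c40 (others 0.126 to 0.281), 14.9 of Pdk4 (others 33.2 to 35.3) and 123 of Cidec (others 143.7 to 145.7). In the chow group, replicate 1 had 9.21 CPM of Cyp2c69 (others 0.932 to 1.99), 20.4 of Cyp2c40 (others 3.73 to 5.99) and 1.55 of Npas2 (others 0.478 to 0.648). Chow replicate 2 had an erythroid score of −0.37 (others 0.18 to 0.26), 38 CPM of Cela2a (others 0.378 to 0.677) and 0.208 of Acod1 (others 0.101 to 0.118). Chow replicate 3 had 0.0504 CPM of Aqp7 (others 0) and 3.3 of Il1rn (others 2.56 to 2.61), and chow replicate 4 had 80.3 of Srebf2 (others 59.7 to 62.4) and 258 of Msmo1 (others 95.5 to 119). No explanation was tested for these values.

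Genes changed in MASH against chow differed between the compounds in the opposite direction in 95.4% of cases. The share was 94.9% without both libraries that carried pancreatic transcripts, so it did not rest on those libraries. Fewer genes were called between the compounds without them, as given above. The share says no more about its source, since other splits of the compound libraries also gave high shares. Wrong titles could not be judged from the share. It was 91.1% without both libraries whose tag and title disagreed, but other splits of the compound libraries reached 93.7%. With groups from the tags the share was 82.3%, and edgeR called 0 genes between the compounds. Under a larger share of hepatocytes that dilutes other cell types alike, the macrophage and endothelial scores would move together. Their difference was lower with C18:1-leucine by −1.05 (0.14 ± 0.17 against 1.2 ± 0.43). The exact permutation p was 0.057 (two-sided, 35 splits), so this explanation was not excluded. Fewer macrophages alone, which would raise other cell types alike, are argued against as the whole cause, because the bile acid score moved apart from the endothelial score by 0.63 (0.24 ± 0.06 against −0.39 ± 0.02; exact permutation p = 0.029, two-sided, 35 splits). The lists in both tests had already been compared between these groups, so neither test is independent of those results. Each of these tests weighed 1 uniform change of cell shares, and combined changes were not tested. How much either compound contributes and whether the doses differed stay open.

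In C18:1-leucine against MASH, edgeR called 11 genes where DESeq2 called 938 and limma voom 617. Many adjusted p-values lay just above the threshold: 345 genes had an edgeR adjusted p of 0.05 to 0.10. Whether a wider spread from MASH replicate 4 lowered the count could not be told from leaving it out. Without it edgeR called 6 genes, but fewer MASH libraries remained, and without MASH replicate 3 it called 0. The low count may come in part from where the threshold falls among the 345 genes. The rest of the difference between the tools stays open.

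Erythroid transcripts were higher with C18:1-leucine than with C18:1, by a median of 1.45. C18:1-leucine replicate 1 is argued against as the only source, since the median was 1.29 without it, but the genes called fell from 7 to 1, and to 1 also without C18:1-leucine replicate 2 or C18:1 replicate 1, 3 or 4. The groups overlapped, with 639 CPM in C18:1-leucine replicate 4 and 783 in C18:1 replicate 2. More blood left in the tissue may be the source and stays open: in 1 of the 3 C18:1-leucine libraries the neutrophil and erythroid scores were both above those of the 4 C18:1 libraries. Neutrophil transcripts in C18:1-leucine replicates 2 and 4 went the other way, at 6.04 and 6.54 CPM against 17.97 to 31.75 with C18:1. Differences in perfusion or in blood formation were not tested.

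For 4 counts of genes, 1 of 35 splits of the libraries, the real one, gave as many. That is the smallest share 35 splits allow. These tests were chosen after the results were seen and were not adjusted for their number. Chance is thus less likely as the source of these counts but not excluded. The real count and the highest of the other splits were 5563 and 2196 for MASH against chow, 2544 and 1825 for C18:1-leucine against C18:1, 8252 and 1 for C18:1 against chow, and 2276 and 0 for C18:1-leucine against chow. For C18:1 against MASH edgeR called 0 genes (968 with an unadjusted p under 0.05, DESeq2 2, limma voom 0), and 35 of 35 splits gave as many. The highest of them called 630 genes and set MASH replicate 4 and C18:1 replicates 1, 3 and 4 against MASH replicates 2 and 3 and C18:1 replicate 2, which points to a structure of the samples that the groups do not follow. For C18:1-leucine against MASH the 10 splits were too few for a share under 0.05, with 11 genes in the real split, the only 1 of 10 with as many, and 0 in the highest other.

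For the counts of lists at the preset correlation, chance was not excluded. As many lists were called in 13 of 35 splits for MASH against chow (16 in the real split, 21 in the highest other), in 12 of 35 for C18:1 against MASH (15 and 19) and in 20 of 35 for C18:1-leucine against C18:1 (15 and 23). For C18:1-leucine against MASH, 2 of 10 splits gave as many (17 and 18), too few splits for a share under 0.05.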

How the results depend on the processing

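The setting without both libraries with pancreatic transcripts was chosen after seeing the data. Of the named genes called, 91 of 114 in MASH against chow, 0 of 10 in C18:1-leucine against MASH and 0 of 84 in C18:1-leucine against C18:1 kept direction and call under every alternative except the 2-fold minimum, as did 1 of 16, 0 of 17 and 2 of 15 called lists and 0 of 15 in C18:1 against MASH. The 2-fold minimum was applied to the counts of genes only, so genes changed less than 2-fold, such as Alb, are among the 91. A fold of at least 2 left 2075 genes for MASH against chow, 7 for C18:1-leucine against MASH, 643 against C18:1, 3095 for C18:1 against chow and 912 for C18:1-leucine against chow, by construction. For C18:1 against MASH DESeq2 gave 2 genes. For C18:1-leucine against MASH the count was 30 without a filter, 938 with DESeq2, 617 with limma voom, 51 with 2 groups alone, 35 with a replicate block, 0 with groups from the tags, 0 without both libraries whose labels disagreed and 0 without both with pancreatic transcripts. Against C18:1 it was 4458 with limma voom, 1621 with 2 groups alone, 0 with groups from the tags, 487 without both libraries whose labels disagreed and 593 without both with pancreatic transcripts. For C18:1-leucine against chow it was 653 with groups from the tags and 1049 without both with pancreatic transcripts. The replicate numbers did not pair the libraries, and the replicate block gave 5249 genes for MASH against chow. An estimated correlation left 1, 0, 0 and 2 lists in the 4 main comparisons, and fry 0 for C18:1 against MASH and 8 for C18:1-leucine against MASH. With groups from the tags the opposite share was 82.3%, Moxd1 in C18:1-leucine against C18:1 was −2.69, Mup16 −1.25, Mup9 −0.53 and Slc4a1 −0.61, and Ctrb1 ranged from −1.51 (without C18:1-leucine replicate 2) to 13.84 with 1 library left out. With groups from the tags the list medians of C18:1 against MASH were 0.06 for bile acids, 0.06 for branched-chain amino acids, 0 for N-acyl enzymes, −0.18 for collagens, 0 for chemokines, −0.07 for macrophages, −0.17 for T and NK cells, −0.23 for B cells, −0.07 for stellate cells, −0.32 for cholangiocytes, 0.16 for hepatocytes, 0.35 for acute phase, −0.46 for cell cycle, 0.07 for the respiratory chain and 0.66 for erythroid genes, and with 1 library left out acute phase ranged from −0.35 to 0.54 (without MASH replicate 3). In C18:1-leucine against MASH the PPARα list ranged from −0.14 to 0.15 (without MASH replicate 2) and neutrophils from −1.33 (without C18:1-leucine replicate 1) to 1.48 with 1 library left out, and neutrophils were −1.32 with groups from the tags and −1.3 without both libraries whose labels disagreed. With 1 library left out, gene counts ranged from 3811 (without MASH replicate 4) to 5730, 0 to 0 (edgeR), 0 to 61, 756 (without C18:1-leucine replicate 2) to 3043, 6953 to 8522 and 976 (without C18:1-leucine replicate 4) to 2427. List counts ranged from 15 to 17, 12 to 16, 17 to 21 and 13 to 20, and the opposite share from 93.1% to 96.3%. Fewer samples explain part of these changes, and the cause of the others was not tested.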
